A study of Homo sapiens with 4 samples.

How the data were processed

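RNA was measured by sequencing in 4 libraries, 1 each from untreated cells and from cells given chidamide, decitabine, or both drugs. The labels name the cells as Jurkat, an established human T cell leukaemia line, carrying a KMT2D variant. Chidamide inhibits histone deacetylases, and decitabine is a nucleoside analogue that traps DNA methyltransferases. The labels give the chidamide dose as 5 nm and the decitabine dose as 5 µm, with the units as the labels write them. Whether these stand for nanomolar and micromolar, and whether the doses are the right way round, is uncertain, which limits what the drug arms can be taken to show. The treatment time was not used here because the labels do not give it. Total RNA was depleted of ribosomal RNA and made into stranded libraries.

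Per the labels, the authors trimmed reads with cutadapt 1.9, aligned them to the hg19 genome with HISAT2 2.0.4, and quantified them with Cufflinks and Cuffdiff. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each library, as the authors computed it. The count columns of the deposited table hold a scaled signal, because the authors' estimated fragments were divided by a library factor. In these columns low values fell on multiples of a step, which put the worth of 1 fragment at 1.90 in the untreated, 0.993 in the chidamide, 1.01 in the decitabine and 0.811 in the combination library. Between 83.7% and 86.2% of the values worth 0.5 to 100 fragments lay within 0.02 of a whole number after division by the step, so the fragments are estimates and were used for depth and counting error. The length column equalled the span of each locus and was not used as a transcript length.

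The table held 20314 entries, all protein coding, with 20232 gene symbols. FPKM was summed for the 81 symbols that had several entries. Genes with at least 1 FPKM in at least 1 library were analysed, which left 12116 genes. Changes were differences of log2(FPKM + 1), and a gene was counted as higher or lower at a difference of at least 2-fold on this scale. Of the genes analysed, 42.2% lay in a locus that the table shares between several genes, where fragments may be divided between neighbours.

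The protein coding fragments came to 6189826 in the untreated, 11594596 in the chidamide, 11628591 in the decitabine and 14257673 in the combination library. Errors given for log2 changes are standard errors from counting alone. Ratios against a library with 1 to 3 fragments carry an exact 95% interval (Clopper-Pearson) on the scaled counts. A ratio against 0 fragments is a lower bound with 3 fragments as the floor of that library. These errors, intervals and floors cover counting error only.

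With 1 library per condition there was no replicate check, so no test was run on any gene and no p-value is given. Each drug and the combination were compared with the untreated library, and the combination with each drug. The departure of the combination from the sum of the log2 changes of the drugs was computed per gene. Correlations of changes were computed across genes, which are not independent replicates, beside values simulated with no effect and equal noise in each library.

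Before the data were examined, 37 gene lists were fixed, among them markers of other blood cell types. Each list's median change was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is called set apart where it fell under percentile 2.5 or over percentile 97.5, and a list with fewer than 5 measured members gets values only. Bootstrap intervals for list medians used 2000 draws over members. The list of nuclear long noncoding RNAs had 0 members in the table and was not analysed here.

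Genes were named by a rule fixed at the same time. It takes the 8 largest differences in each direction against the untreated library, and the 5 largest in each direction for the combination against each drug and for the departure, among genes with at least 5 FPKM in a compared library. It adds up to 4 members with the largest change in each list, and always HDAC1, HDAC2, HDAC3, HDAC10, DNMT1, DNMT3A, DNMT3B, KMT2D and SPI1. Some genes that the rule takes are not reported here. Genes named outside it are said to have been chosen after their values were seen.

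Alternatives fixed in advance were pseudocounts of 0.1 and 5, no expression filter, a filter at 5 FPKM, median ratio scaling, scaling of the libraries to a common sum, the highest entry for a repeated symbol, and a locus span of at least 500 bases. Chosen after seeing the data were genes alone in their locus, an effective length of at least 500 bases, libraries thinned to equal fragments, and scaled counts plus 20 in place of FPKM plus 1. The pathway names in the deposited table were examined after the fixed lists, with 2000 random lists for each of 221 pathways of at least 15 measured genes. The calculations were tested on simulated data with known changes. In the simulated decitabine comparison 29 of 11518 unchanged genes passed 2-fold by counting alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Positions are hg19 coordinates from the deposited table, counted from 1.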

Results

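Messenger RNA levels were compared between untreated cells and cells given chidamide, decitabine, or both drugs, with 1 library per condition. The labels name the cells as Jurkat, a T cell leukaemia line. The untreated library held 6189826 protein coding fragments, the chidamide library 11594596, the decitabine library 11628591 and the combination library 14257673. Genes at or above 1 FPKM numbered 10736 in the untreated, 11678 in the chidamide, 10667 in the decitabine and 11622 in the combination library. Libraries with the same chidamide status were the most alike. Pearson's r across 12116 genes was 0.990 between untreated and decitabine and 0.992 between chidamide and the combination, against 0.912 to 0.913 between libraries that differed in chidamide.

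All 4 libraries carried high levels of erythroid genes and little RNA from most T cell genes. The fetal globin genes HBG2 and HBG1 stood at 7523 and 1839 FPKM in the untreated library, the embryonic globin genes HBZ and HBE1 at 1325 and 590 FPKM, and the erythroid regulators GATA1 and KLF1 at 284 and 174 FPKM. ALAS2, the erythroid enzyme of haem synthesis, stood at 62.9 FPKM. Of 6 core T cell genes, namely CD2, CD3E, CD247, CD28, LCK and BCL11B, each had 0 fragments in the untreated library, and their highest level anywhere was 0.267 FPKM, for LCK in the combination library. Other T cell genes were present in the untreated library, among them CD3D at 86.0 FPKM, CD7 at 41.5 FPKM and CD3G at 6.14 FPKM (48 fragments). In the list of T cell receptor and T lineage genes 12 of 41 members reached 1 FPKM in untreated cells, and in the erythroid and megakaryocyte list 17 of 20 did. The 6 core genes and the erythroid genes of this paragraph were chosen after their values were seen.

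**Figure D1:**
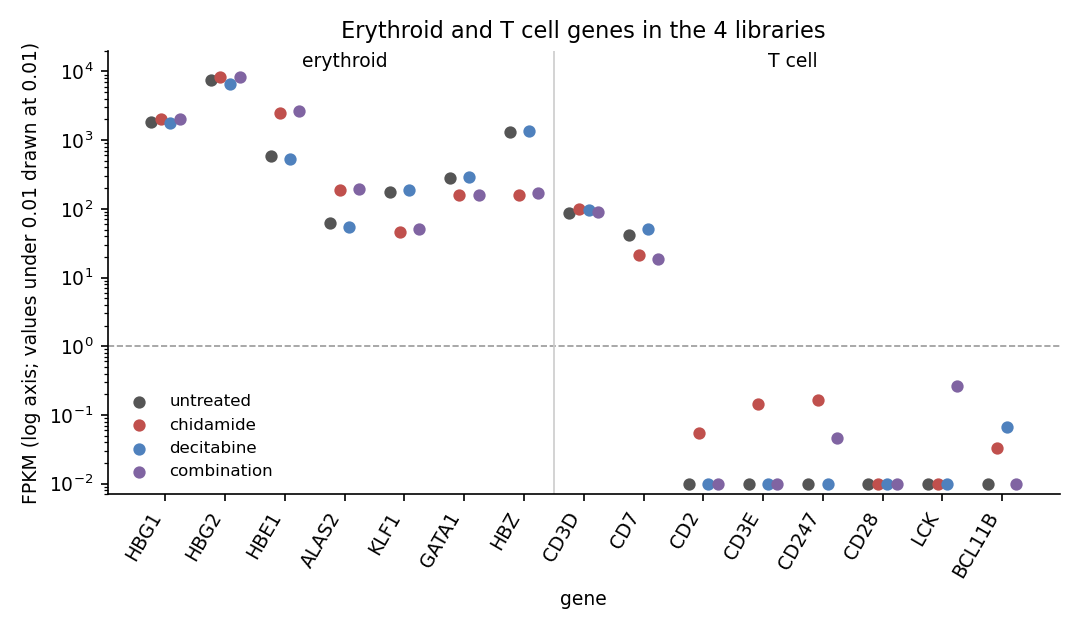
Level in FPKM (log axis, values under 0.01 drawn at 0.01) of 7 erythroid and 8 T cell genes in each of the 4 libraries, 1 point per library, with a dashed line at 1 FPKM. All 7 erythroid genes, CD3D and CD7 lie above the line in every library, and the 6 core T cell genes lie below it, at 0.267 FPKM or less.

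The comparison of chidamide with untreated cells addresses what a histone deacetylase inhibitor does to gene expression. Chidamide cells had 1606 genes at least 2-fold higher and 710 at least 2-fold lower than untreated cells, and 850 of the higher genes (52.9%) were under 1 FPKM in untreated cells. With a pseudocount of 5, which weighs down low levels, 595 were higher and 340 lower. CLU, which encodes the secreted chaperone clusterin, was 104-fold higher, at 404 against 3.90 FPKM (log2 change 6.37 ± 0.22, counting SE). CDKN1A, the cyclin-dependent kinase inhibitor p21, was 47.6-fold higher, at 101 against 2.11 FPKM (5.03 ± 0.19). IFITM1, an interferon-inducible membrane protein, was lower, at 93.2 against 964 FPKM (-3.36 ± 0.06), and so was PSAT1, an enzyme of serine synthesis, at 9.09 against 94.7 FPKM (-3.25 ± 0.09). CLU (ENSG00000120885) lies on chromosome 8 at 27454434 to 27472548, CDKN1A (ENSG00000124762) on chromosome 6 at 36644305 to 36655116, IFITM1 (ENSG00000185885) on chromosome 11 at 307631 to 315272 and PSAT1 (ENSG00000135069) on chromosome 9 at 80912059 to 80945009.

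Several of the other large increases were in genes nearly silent without the drug. CPXM1, a carboxypeptidase-like protein, stood at 171 FPKM in chidamide cells against 2.66 in untreated cells (log2 change 5.56), and COL1A1, a chain of type I collagen, at 59.3 against 0.521 FPKM (5.31). CRYM reached 39.5 FPKM from 1 fragment in untreated cells, a ratio of 278 with a 95% interval of 49.7 to 11010, and FSD1 reached 39.5 FPKM from 2 fragments (ratio 197, interval 54.4 to 1631). L1CAM, a neural adhesion molecule in a locus shared by 5 genes, stood at 48.9 against 0.816 FPKM (4.78). Among the lower genes, CHAC1, which degrades glutathione, stood at 1.48 against 21.9 FPKM (-3.21), and LMO2, a haematopoietic transcription cofactor, at 6.38 against 67.0 FPKM (-3.20). SELPLG, the ligand of P-selectin, stood at 3.42 against 36.4 FPKM (-3.08), HBZ at 159 against 1325 FPKM (-3.05), and GALNT5 at 2.12 against 23.5 FPKM (-2.97). AL158147.2 was listed at 41.7 FPKM in untreated cells from 1 fragment and at 0 elsewhere, so no direction is read from it.

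Over measured members, the list with the highest median was one of genes of another tissue, the neuronal list. The drug itself can decide which members pass the expression filter. In the neuronal list, all 15 measured members lay above 0 and 11 were at least 2-fold higher in chidamide cells, with a median log2 change of 2.24 (2.12 when 2 members silent in untreated cells are set to their bound). Over all 34 members, with no expression filter, the neuronal median was 0.16, still set apart but no longer the highest (myeloid markers 0.59). SYP, a synaptic vesicle protein, stood at 40.9 against 0.647 FPKM, SYN1 at 30.0 against 0.352 FPKM, and VGF at 29.2 against 0.754 FPKM. In the epithelial and mesenchymal list 11 of 23 members were at least 2-fold higher and 2 lower (median 0.97), with the fibronectin gene FN1 at 131 against 20.5 FPKM, COL6A1 at 14.9 against 0.406 FPKM and the transcription factor SNAI1 at 35.7 against 9.16 FPKM. Myeloid markers were higher as a list, with 10 of 15 members at least 2-fold higher and a median of 1.34 (0.87 with 3 silent members at their bound). The median was 0.59 over all 27 members, 0.55 with a pseudocount of 5 and 2.07 with one of 0.1, set apart in each. SPI1, which encodes the myeloid regulator PU.1, stood at 17.4 against 5.98 FPKM (1.40 ± 0.20), and the integrin gene ITGAX at 10.4 against 0.850 FPKM. CSF1R, the receptor of macrophage colony-stimulating factor, stood at 2.91 FPKM against 0.0853 FPKM from 2 fragments.

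Chromatin genes differed by class. Of the replication-dependent histone genes, 26 of 32 were at least 2-fold higher in chidamide cells and 2 lower, with a median log2 change of 1.47. HIST1H4H stood at 181 against 29.9 FPKM, HIST1H2AG at 84.9 against 15.5 FPKM and HIST1H3B at 35.9 against 4.48 FPKM. The replication-independent histone list, which shares 4 genes with the former, had a median of 0.65, with 5 of 12 members at least 2-fold higher and H2AFX at 355 against 133 FPKM. Among 11 histone deacetylase genes 1 was higher and 1 lower (median 0.21, not set apart). HDAC11 stood at 19.9 against 4.44 FPKM and HDAC7 at 31.2 against 68.2 FPKM. Of the deacetylases that the drug targets, HDAC1 had a log2 change of 0.35 ± 0.05, HDAC2 of -0.65 ± 0.06 and HDAC3 of 0.53 ± 0.07, and HDAC10 had 0.07 ± 0.13. Among 13 DNA methylation and decitabine handling genes 2 were higher (median 0.11, not set apart). CDA, the cytidine deaminase that inactivates decitabine, stood at 10.0 FPKM against 0 fragments in untreated cells, at least 16.0-fold higher, and DNMT3L at 6.78 against 0.367 FPKM. DNMT1 had a log2 change of -0.61 ± 0.04, DNMT3A of -0.43 ± 0.15 and DNMT3B of 0.35 ± 0.08. KMT2D (ENSG00000167548), the histone H3 lysine methyltransferase whose variant the labels name, had a log2 change of -0.63 ± 0.05 from 19.1 FPKM, in a locus shared by 3 genes. COMPASS methyltransferase genes had a median of -0.38 with 0 of 17 past 2-fold, and Polycomb components a median of -0.05 with 1 of 18 lower, PHF19 at 55.8 against 262 FPKM, and neither list was set apart.

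Cell cycle lists parted in direction. Replication and S phase genes had a median log2 change of -0.35, with 3 of 40 at least 2-fold lower, among them the thymidylate synthase gene TYMS at 46.3 against 212 FPKM and MCM5, a subunit of the replicative helicase, at 59.4 against 152 FPKM. Mitotic genes had a median of 0.23, with 3 of 38 at least 2-fold higher, among them CDC20 at 191 against 76.7 FPKM and PTTG1 at 452 against 220 FPKM, while BUB1 stood at 64.6 against 123 FPKM. CDK inhibitors had a median of 0.92 with 2 of 5 higher, CDKN1A and CDKN2D, the latter at 24.5 against 4.93 FPKM, and a median of 0.00 with its unexpressed members. The p53 target list had a median of 0.46 with 6 of 23 higher, among them BTG2 at 50.7 against 10.9 FPKM and the death receptor gene TNFRSF10B at 101 against 30.4 FPKM. As fixed, the p53 target list shares CDKN1A with the CDK inhibitors, and BAX, BBC3 and PMAIP1 with the pro-apoptotic list, so these lists are not independent. DNA repair genes had a median of -0.33 with 0 of 29 past 2-fold and were not set apart. Thinned to equal fragments, the replication list was no longer set apart (percentile 9.25).

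The list furthest below the rest was the ATF4 and unfolded protein response list, the genes cells use in amino acid shortage and protein folding stress. Of its 25 measured members 12 were at least 2-fold lower in chidamide cells and 0 higher, with a median log2 change of -0.90. Beside PSAT1 and CHAC1, the pseudokinase gene TRIB3 stood at 10.9 against 63.3 FPKM and the cystine transporter gene SLC7A11 at 0.701 against 6.70 FPKM. Nuclear-encoded oxidative phosphorylation genes had a median of -0.43 with 2 of 55 lower, among them UQCRC1 at 89.6 against 200 FPKM. Ribosome biogenesis genes had a median of -0.42 with 2 of 29 lower, among them CAD, which starts pyrimidine synthesis, at 20.5 against 43.3 FPKM, and were not set apart over genes alone in their locus (percentile 3.69). Cytosolic ribosomal protein genes lay slightly higher, with a median of 0.11 and 0 of 71 past 2-fold. Mitochondrially encoded mRNAs had a median of 0.13 (0 of 13 past 2-fold), glycolysis genes -0.30 (2 of 20 higher and 2 lower), cholesterol genes -0.24 (1 of 24 higher and 2 lower) and heat shock genes -0.03 (1 of 14 higher), and none of these 4 lists was set apart.

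Signalling, immune and death genes gave mixed lists. ERK output genes had a median log2 change of 0.44, with 7 of 20 higher and 2 lower, and the immediate early genes FOS and EGR1 stood at 30.4 against 1.49 and 137 against 17.0 FPKM. This list was no longer set apart with a pseudocount of 5 (percentile 89.9) or with scaled counts (95.7). T cell activation genes had a median of 0.59 with 5 of 14 higher and 1 lower, with EGR1 in both lists and BIRC3 at 17.8 against 1.98 FPKM, and a median of 0.00 once unexpressed members were counted. In the T lineage list, with a median of 0.32 and not set apart, 5 of 14 measured members were higher and 2 lower, the chemokine receptor gene CCR7 at 40.1 against 1.59 FPKM and RUNX1 at 70.2 against 21.1 FPKM being higher. The erythroid list had 4 of 17 higher and 3 lower (median 0.14, not set apart), with HBE1 at 2509 against 590 FPKM in a locus shared by 19 genes and KLF1 at 45.9 against 174 FPKM. Interferon-stimulated genes had 7 of 24 higher and 3 lower (median 0.26), with IFI6 at 84.6 against 3.99 FPKM. HLA class I and antigen processing genes had 2 of 9 higher and 2 lower (median 0.46), with the immunoproteasome gene PSMB9 at 48.5 against 2.33 FPKM and the peptide loading gene TAPBP at 16.4 against 65.7 FPKM. Cancer-testis genes had 2 of 10 higher and 1 lower (median -0.24), MAPK components 4 of 45 higher and 2 lower (median -0.05), and NOTCH genes 2 of 13 higher (median 0.36). None of these last 5 lists was set apart. By the pathway names examined later, the larger MAPK signaling pathway lay above random lists (median 0.11, 33 of 175 higher and 5 lower). The Notch signaling pathway had a median of -0.19 over 37 genes and did not lie outside (percentile 7.05).

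Pro-apoptotic BCL2 family genes were set apart at a median log2 change of 0.47, with 1 of 12 at least 2-fold higher, BMF at 14.5 against 2.26 FPKM, but not with a pseudocount of 5 (percentile 96.0). Anti-apoptotic genes had a median of -0.08 with 2 of 10 higher, BIRC3 and MCL1, the latter at 103 against 48.7 FPKM. Death receptors and caspases had a median of 0.00 with 1 of 15 higher, TNFRSF10B, and neither list was set apart. Of 13 HLA class II genes and 13 B cell markers, 4 in each list passed the expression filter, which the drug itself can decide, and 3 of these 4 were at least 2-fold higher in each list, such as HLA-DPA1 at 3.67 FPKM (at least 7.32-fold above 0 fragments) and the B cell receptor gene CD79B at 6.71 FPKM (at least 12.2-fold above 0 fragments). In all, 12 of 34 lists were set apart above and 4 below, where 1.70 would fall outside if list members moved independently.

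**Figure D2:**
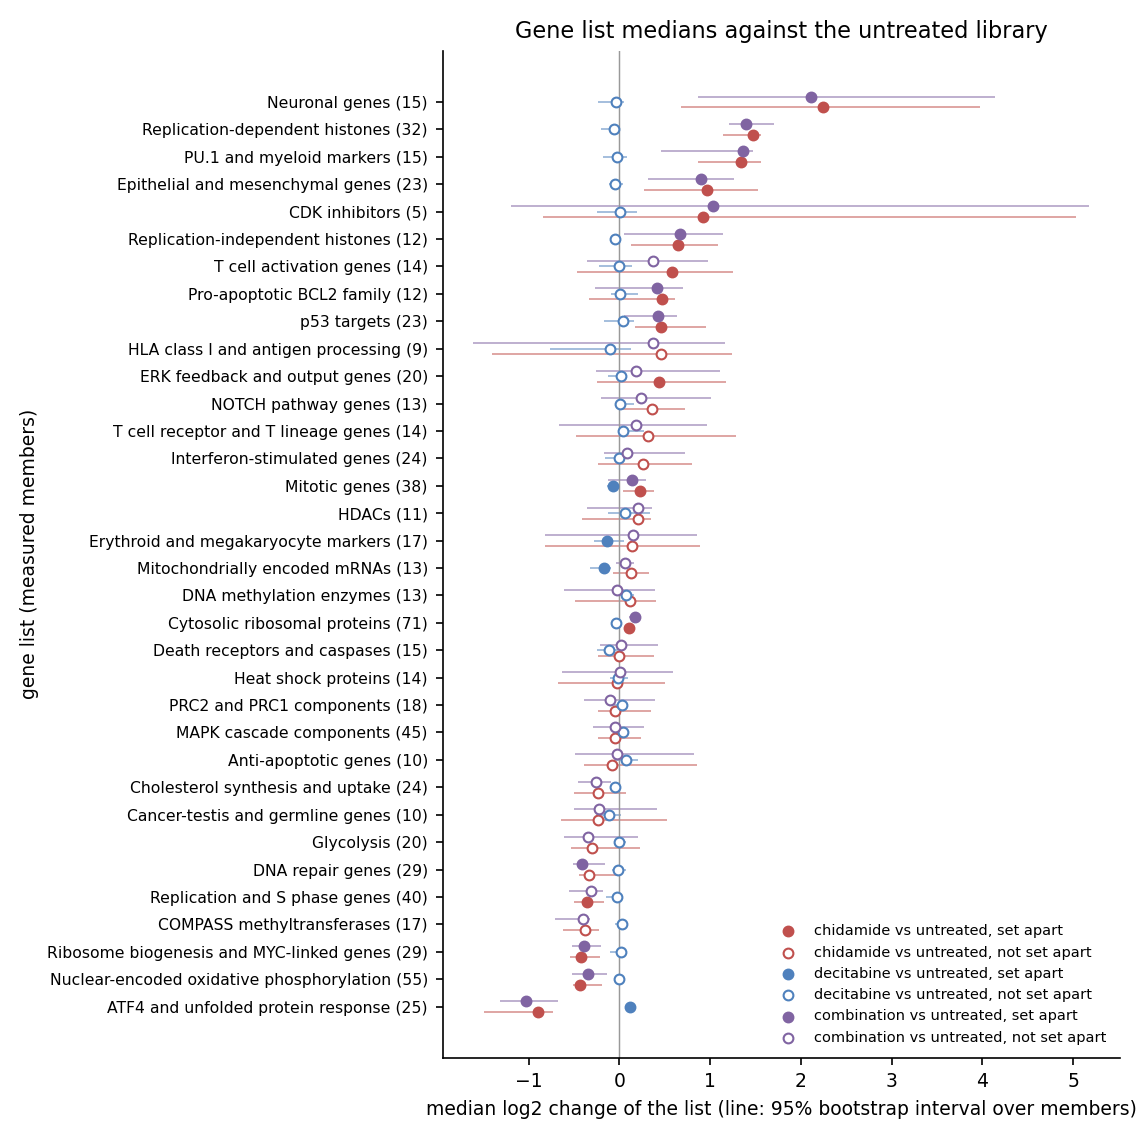
Median log2 change of each of 34 gene lists (number of measured members in brackets) in chidamide, decitabine and combination cells against untreated cells, with filled points for lists set apart from random lists, open points for the others, and lines for the 95% bootstrap interval over members. The neuronal list lies highest at 2.24 with chidamide, the ATF4 list lowest at -0.90, and the decitabine medians lie between -0.17 and 0.12.

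The comparison of decitabine with untreated cells addresses what a DNA methyltransferase inhibitor does to gene expression. Decitabine cells differed little from untreated cells, with 69 genes at least 2-fold higher and 79 at least 2-fold lower. The spread of log2 changes (robust SD) was 0.21, against 0.70 for chidamide. VAMP7, a vesicle fusion protein (ENSG00000124333, chromosome X at 155110943 to 155173433), stood at 1.74 against 20.5 FPKM (-2.97 ± 0.19), with 29 against 315 fragments. It was also low with chidamide (2.43 FPKM) and the combination (2.19 FPKM), so it was high in the untreated library alone. With 1 library per condition an oddity of that library cannot be told apart from an effect of each drug. No list had a member past 2-fold except the MAPK components, where MAPK7 stood at 5.41 against 2.10 FPKM. Cancer-testis genes, which are often silenced by DNA methylation, had a median log2 change of -0.11 with 0 of 10 past 2-fold and were not set apart. The table holds 36 members of this list, and those outside the 10 stayed under 1 FPKM in every library. The median therefore describes only members that were expressed in some library.

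The other named genes of this comparison had few fragments, lay in shared loci, or had changes in FPKM that their fragments did not show. ALG14 had a log2 change of 2.87 from 0.630 FPKM with 24 against 16 fragments, and its change with scaled counts in place of FPKM was -0.21. KCNQ5, a potassium channel gene, stood at 6.50 against 1.97 FPKM (1.34) with 115 against 48 fragments, where the decitabine library was the deeper. PTP4A1 stood at 13.1 against 57.8 FPKM (-2.06) with 656 against 356 fragments, and UBE3D at 4.89 against 26.9 FPKM (-2.24) with 114 against 61. COX6B2 stood at 2.16 against 19.6 FPKM (-2.71) and had a change of 0.06 with scaled counts. CTD-2192J16.22, MINOS1-NBL1, HIST1H2AD, MEF2BNB-MEF2B, ZNF791 and CASK, with changes of 2.75, 2.56, 1.39, 1.36, 1.22 and 1.14, and CHURC1-FNTB and SULT1A4, with -2.88 and -2.49, all lie in loci shared by several genes. C1orf134 had 3 fragments in untreated and 0 in decitabine cells. With scaled counts 10 genes were higher and 13 lower, 18 of them among the 148 called on FPKM.

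Of 34 lists 4 were set apart with decitabine, where 1.70 would fall outside if list members moved independently. Members of a list can move together between libraries, so more than this may fall outside without a drug effect. ATF4 and unfolded protein response genes had a median log2 change of 0.12, with 21 of 25 above 0 and PPP1R15A at 98.7 against 77.9 FPKM. Mitochondrially encoded mRNAs had a median of -0.17, with 13 of 13 below 0 and MT-CO2 at 2408 against 3021 FPKM. Mitotic genes had a median of -0.07, with 10 of 38 above 0, and erythroid genes of -0.14, with 6 of 17 above 0. For the erythroid list the median turned to 0.08 over genes alone in their locus, where the mitotic list was at percentile 2.59. The drug targets had log2 changes of -0.14 ± 0.04 for DNMT1, 0.37 ± 0.14 for DNMT3A and 0.04 ± 0.08 for DNMT3B. The errors cover counting only, while the spread (robust SD) of changes over all genes in this comparison was 0.21. The deacetylases HDAC1, HDAC2, HDAC3 and HDAC10 had -0.13, -0.11, 0.06 and 0.42, KMT2D had 0.09 ± 0.05, and SPI1 had -0.09 ± 0.23. Interferon-stimulated genes had a median of -0.01 with 0 of 24 past 2-fold.

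The comparison of the combination with untreated cells addresses the joint effect of the drugs. Combination cells had 1578 genes at least 2-fold higher and 782 at least 2-fold lower than untreated cells, close to the counts with chidamide alone. CLU stood at 431 against 3.90 FPKM (log2 change 6.46 ± 0.22) and CDKN1A at 112 against 2.11 FPKM (5.18 ± 0.19). CPXM1, COL1A1, CRYM and FSD1 were again among the 8 largest increases, with changes of 5.57, 5.49, 5.19 and 4.96, and CD9, a tetraspanin gene, stood at 42.7 against 0.560 FPKM from 2 fragments (ratio 117, interval 32.3 to 971). SELPLG (-3.60), IFITM1 (-3.59), PSAT1 (-3.18), CHAC1 (-3.17) and LMO2 (-3.06) were again among the lowest. They were joined by INHBE, an inhibin chain gene, at 0.221 against 9.95 FPKM (-3.17), and by the mucin gene MUC1, at 11.4 against 103 FPKM (-3.07).

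Most lists set apart with chidamide were also set apart in the combination, but ERK output (median log2 change 0.18, percentile 82.9), replication (-0.32, percentile 4.45) and T cell activation genes (0.37, percentile 95.1) were not. Set apart above were the neuronal (median log2 change 2.11), replication-dependent histone (1.40), myeloid (1.37, or 0.90 with 2 silent members at their bound), CDK inhibitor (1.04), epithelial and mesenchymal (0.90), replication-independent histone (0.67), p53 target (0.43), pro-apoptotic (0.42), cytosolic ribosomal protein (0.18) and mitotic (0.14) lists. Those set apart below were the ATF4 and unfolded protein response list (-1.02, with 13 of 25 lower), DNA repair (-0.41), ribosome biogenesis (-0.38) and oxidative phosphorylation (-0.34). Thinned to equal fragments, the pro-apoptotic, ribosome biogenesis and DNA repair lists were no longer set apart (percentiles 96.7, 3.08 and 3.85). With no expression filter the CDK inhibitor median was 0.00 (percentile 60.1) and the neuronal median 0.21. SPI1 stood at 17.0 FPKM (1.37 ± 0.20) and KMT2D at 10.4 FPKM (-0.82 ± 0.05). HDAC1, HDAC2, HDAC3 and HDAC10 had changes of 0.34, -0.77, 0.61 and 0.21. DNMT1 had -0.80 ± 0.04, DNMT3B 0.30 ± 0.08, and DNMT3A -1.08 ± 0.14, at 3.48 against 8.49 FPKM. Median ratio scaling moved the median change of all genes from -0.02 to 0.08, and the genes and set apart lists named here kept their direction.

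Against decitabine alone, the combination had 1562 genes at least 2-fold higher and 712 lower. This comparison shares no library with that of chidamide against untreated cells, and the changes in both correlated across 12116 genes (Pearson's r 0.905, Spearman's rho 0.864). Both comparisons had 1249 genes higher and 464 lower, where 207 and 41.7 would be shared if the calls were independent, and 5 genes were called in opposite directions. The largest increases were CLU (log2 change 6.73), CPXM1 (6.30), CD9 (at least 147-fold above 0 fragments), CDKN1A (5.42) and CYP4F2, a fatty acid hydroxylase gene, at 47.4 FPKM against 0.265 FPKM from 1 fragment. The largest decreases were IFITM1 (-3.54), SELPLG (-3.49), ALG14 (-3.30), CHAC1 (-3.26) and MUC1 (-3.22), of which ALG14 had 19 against 24 fragments. Of the 34 lists 10 were set apart above and 3 below, among them the erythroid list at 0.34, which turned to -0.26 over genes alone in their locus. Oxidative phosphorylation genes, set apart below, were not so over genes alone in their locus (percentile 7.75). Of those above, myeloid markers were not set apart with scaled counts (95.5), nor CDK inhibitors with no expression filter (60.2).

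**Figure D3:**
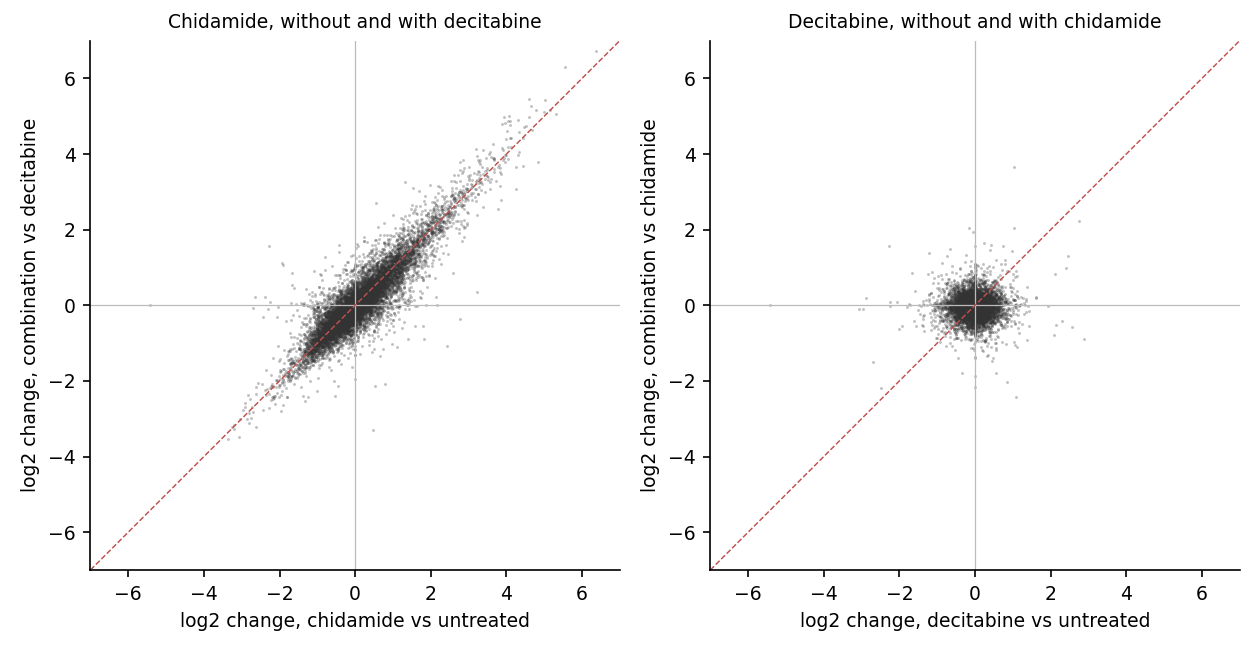
Log2 change of each of 12116 genes (1 point per gene), on the left for chidamide against untreated (horizontal) and the combination against decitabine (vertical), on the right for decitabine against untreated (horizontal) and the combination against chidamide (vertical), with dashed lines where the changes are equal. The points on the left follow the line (Pearson's r 0.905) and those on the right gather around 0 (Pearson's r 0.04).

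Against chidamide alone, which asks what decitabine adds, the combination had 35 genes at least 2-fold higher and 35 lower. SEMA4D, a semaphorin gene, stood at 8.34 against 2.34 FPKM (log2 change 1.49) with 166 against 129 fragments, a ratio of 1.05 in scaled counts. KM-PA-2 stood at 5.13 against 1.01 FPKM (1.61), and RP11-598P20.5 at 5.24 against 0.639 FPKM (1.93), both in shared loci, as were AL035252.1 (3.66) and AC006449.1 (2.05), which had 0 and 3 fragments with chidamide. The 5 lowest were SULT1A4 (-2.18), CXorf65 (-2.03), MRPL30 (-1.78), COX6B2 (-1.50) and RRAGB (-1.21). Of these COX6B2 had 198 against 196 fragments and RRAGB 43 against 51, where the combination library was the deeper. With scaled counts 5 genes were higher and 4 lower. Of the 34 lists 1 was set apart above, the cytosolic ribosomal proteins, and 4 below, the mitochondrially encoded mRNAs, mitotic, cholesterol and glycolysis genes. Over genes alone in their locus the ribosomal protein, cholesterol and glycolysis lists were no longer set apart (percentiles 93.8, 5.30 and 6.89).

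Changes with decitabine in the absence and presence of chidamide, which share no library, were nearly unrelated across genes (Pearson's r 0.04, Spearman's rho 0.03). The genes called in the same direction in both were AC069368.3, AL035252.1, CMTM1 and CTD-2192J16.22, which were higher, and COX6B2 and SULT1A4, which were lower, all 6 in shared loci and chosen after their values were seen. If the calls were independent 0.199 and 0.228 would be shared, and 5 genes were called in opposite directions. With scaled counts COX6B2 had a decitabine change of 0.06. Chidamide and decitabine changes, which share the untreated library, had an r of 0.15 and a covariance of 0.0424, against 0.499 and 0.0311 in simulation with equal noise and no effect. The simulated r holds no chidamide effect, so it is not a baseline for the observed r. Both comparisons had 24 genes higher and 30 lower, against 9.32 and 9.91 in simulation and 9.15 and 4.63 if the calls were independent. The untreated library was the shallowest, so equal noise can understate what the shared library brings. Whether it accounts for part or all of this excess cannot be told.

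The combination departed from the sum of the single drugs by at least 2-fold in 295 genes, 145 above and 150 below. Of these, 107 were also past 2-fold for decitabine against untreated. Leaving aside AL158147.2, which rests on 1 fragment, the largest departures above were CHURC1-FNTB (3.07), C1orf134 (2.97, from 3 untreated fragments), VAMP7 (2.86 ± 0.27) and AL035252.1 (2.63). VAMP7 was low in each treated library, so the sum of the drugs lay far below the combination. The largest below were ALG14 (-3.76), MINOS1-NBL1 (-3.13), CXorf65 (-2.87), GNAQ (-1.69 ± 0.15) and CLDND2 (-1.57). GNAQ, a G protein subunit gene, stood at 6.95, 9.84 and 4.53 FPKM in untreated, chidamide and combination cells and was highest with decitabine alone. With scaled counts 27 genes lay above the sum and 28 below, and ALG14 had a departure of 0.12.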

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

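Over the 5 comparisons 52 list medians were set apart, and these were recomputed under each alternative, other lists not. They kept their sign wherever they had a value, except 2 medians of 1 list that turned and 4 that came to 0. Of 353 named changes of at least 2-fold, those that had a value (252 over genes alone in their locus, 313 at 5 FPKM, 327 with an effective length limit, 350 with a span limit, 352 after thinning) kept their sign, except 3, in 2 genes, with scaled counts. Of 422 smaller named changes, 30 had the opposite sign with scaled counts, 5 after thinning and 2 with scaling to a common sum, all in the comparisons of decitabine with untreated and of the combination with chidamide. Of the values printed above this takes away the direction of DNMT3B (with scaled counts) and SPI1 (after thinning) with decitabine. All 12 counts of genes past 2-fold moved by over 1.5 times with a pseudocount of 5 and over genes alone in their locus, 9 at 5 FPKM, and 6 each with a pseudocount of 0.1 and with scaled counts. Of the 12116 genes, 7005 were alone in their locus and 9513 reached 5 FPKM. Counts fall in these settings because genes are removed, so their movement is no sign by itself that the share of changed genes differs. Of the alternatives, 4 were chosen after seeing the data, namely genes alone in their locus, effective length, thinning to equal fragments and scaled counts. Depth, at 6189826 fragments in the untreated library, limits what can be said of low genes, and the cause of the differences was not tested except where the setting itself removes genes.

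With a pseudocount of 0.1, decitabine had 297 genes higher and 374 lower than untreated, the combination 130 and 177 against chidamide, and departures numbered 493 above and 472 below. The r of chidamide and decitabine changes was 0.197 and that of chidamide with and without decitabine 0.864. Medians were 1.61 for replication-dependent histones with chidamide, and 2.07 and 1.904 for myeloid markers with chidamide and the combination. For the combination against decitabine they were 1.81 for replication-dependent histones and 2.32 for myeloid markers.

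With a pseudocount of 5, genes higher and lower were 595 and 340 with chidamide, 4 and 10 with decitabine, 595 and 371 with the combination, 599 and 356 for the combination against decitabine, and 2 and 3 against chidamide. Departures were 19 above and 8 below, and r with and without decitabine was 0.927. Medians with chidamide were 0.17 for ERK output, -0.28 for replication and 0.24 for pro-apoptotic genes, all no longer set apart, and 0.55 for myeloid markers. With the combination they were 1.13 for replication-dependent histones, and 0.25 for pro-apoptotic and -0.32 for ribosome biogenesis genes, both no longer set apart. Against decitabine the combination had 1.198 for replication-dependent histones and 0.53 for myeloid markers.

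With no expression filter, which brings in unexpressed members, r was 0.894. ERK output (0.27), CDK inhibitors (0 with chidamide and 0 with the combination) and T cell activation genes (0) were no longer set apart, and medians were 0.59 for myeloid markers with chidamide, and 0.16 and 0.21 for neuronal genes with chidamide and the combination. For the combination against decitabine, CDK inhibitors (0) and erythroid genes (0.0967) were no longer set apart, and replication-dependent histones had 1.37, myeloid markers 0.59 and neuronal genes 0.16.

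At 5 FPKM or more, where fewer genes are counted, 957 were higher with chidamide, 21 higher and 34 lower with decitabine, 941 higher with the combination, and 929 higher for the combination against decitabine. Against chidamide there were 11 and 10, and departures were 60 and 54. The r values were 0.117 and 0.932, and ribosome biogenesis with the combination (-0.37) and cytosolic ribosomal proteins for the combination against chidamide (0.0696) were no longer set apart.

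Median ratio scaling gave cytosolic ribosomal proteins 0.21 with chidamide, 0.29 with the combination and 0.35 for the combination against decitabine. Scaling to a common sum gave 60 genes lower for the combination against chidamide and 227 departures below, with medians of -0.0972 for cholesterol genes and 0.0318 for cytosolic ribosomal proteins against chidamide, and 0.17 for the latter against decitabine. The limit on locus span left 52 of 52 list medians and 765 of 765 named changes the same, and the highest entry for a repeated symbol left 52 medians and 774 of 775 the same. Of 775 named changes, 288 moved past their counting error with a pseudocount of 5, 267 with scaled counts besides the 3 that turned, 174 with a pseudocount of 0.1, 107 with median ratio scaling and 46 with a common sum, and 18 of 771 after thinning.

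Over genes alone in their locus, which are fewer and leave 2 list medians without a value, counts were 1013 higher and 411 lower with chidamide, 26 and 40 with decitabine, 1007 and 448 with the combination, 1016 and 405 against decitabine, and 10 and 13 against chidamide, with departures of 71 and 69. The r values were 0.123 and 0.922. The erythroid list with decitabine turned to 0.0791 and for the combination against decitabine to -0.26. No longer set apart were mitotic genes with decitabine (-0.0616), ribosome biogenesis with chidamide (-0.41) and with the combination (-0.39), and pro-apoptotic (0.42) and DNA repair genes (-0.28) with the combination. Nor were oxidative phosphorylation genes (-0.34) for the combination against decitabine, or cholesterol (-0.0356), glycolysis (-0.00178) and cytosolic ribosomal protein genes (0.0663) for the combination against chidamide.

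With an effective length of at least 500 bases, the combination against chidamide had 19 genes higher and 23 lower, r was 0.915, and replication-dependent histones had 1.79 with chidamide. For the combination against decitabine, oxidative phosphorylation genes (-0.36) were no longer set apart and cytosolic ribosomal proteins had 0.17.

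With libraries thinned to equal fragments, the combination against chidamide had 66 genes higher and 70 lower, and r was 0.887. No longer set apart were ERK output (0.21) and replication genes (-0.28) with chidamide, the erythroid list with decitabine (-0.0853), and pro-apoptotic (0.33), ribosome biogenesis (-0.37) and DNA repair genes (-0.36) with the combination, oxidative phosphorylation genes (-0.31) for the combination against decitabine, and cholesterol (-0.0407) and glycolysis genes (-0.00633) against chidamide.

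With scaled counts in place of FPKM, decitabine had 10 genes higher and 13 lower, the combination 5 and 4 against chidamide, and departures were 27 above and 28 below. The r values were 0.0716 and 0.961. ERK output with chidamide (0.36) was no longer set apart, and replication-dependent histones had 1.08 with the combination and 1.18 for the combination against decitabine. In that comparison myeloid markers (0.66) and oxidative phosphorylation genes (-0.30) were no longer set apart, nor were glycolysis genes (-0.00636) against chidamide. ALG14 reversed with decitabine (-0.21) and in its departure (0.12), and COX6B2 with decitabine (0.0648).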

Other observations

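The tests of cell lineage and the pathway medians given here were chosen after the results were seen, while the tests of the decitabine library and of the number of detected genes were set before theirs.

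By the pathway names in the deposited table, 49 of 221 pathways lay above and 13 below random lists in chidamide cells, where 11.1 would fall outside if genes moved independently. Among those below, aminoacyl-tRNA biosynthesis, which charges tRNAs with amino acids, had a median log2 change of -0.38 with 10 of 43 genes at least 2-fold lower, among them WARS at 49.4 against 332 FPKM and AARS at 69.4 against 262 FPKM. Protein processing in the endoplasmic reticulum had a median of -0.44 with 18 of 140 lower and 5 higher, among them the disulfide isomerase gene PDIA4 at 64.5 against 224 FPKM and the stress regulator XBP1 at 29.1 against 75.1 FPKM. N-glycan biosynthesis had a median of -0.42 with 9 of 45 lower and 2 higher, with the oligosaccharyltransferase gene STT3A at 90.0 against 229 FPKM. The folate one carbon pool had a median of -0.50 with 5 of 19 lower and 1 higher. Some pathways did not lie outside where a related fixed list was set apart. Oxidative phosphorylation (107 genes) had a median of -0.25 (percentile 2.975) with chidamide and -0.20 (7.275) with the combination. The p53 signaling pathway (54 genes) had 0.08 (percentile 88.35) and -0.02 (62.65). The genes named in this paragraph and the next were chosen after their values were seen.

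Pathways above included the extracellular matrix receptor genes, with a median of 0.94 and 16 of 41 genes at least 2-fold higher and 3 lower in chidamide cells, among the former COL6A2 at 11.3 against 0.676 FPKM. Cell adhesion molecules had a median of 0.98 with 27 of 56 higher and 5 lower, among the former PTPRF at 41.4 against 6.63 FPKM, while PTPRC, which encodes the leukocyte antigen CD45, stood at 0.968 against 8.06 FPKM. Arachidonic acid metabolism had a median of 0.72 with 10 of 25 higher and 2 lower, among the former the prostaglandin synthase gene PTGES at 22.8 against 0.190 FPKM and the phospholipase gene PLA2G16 at 25.0 against 0.625 FPKM. With decitabine 2 of 221 pathways lay above and 11 below, among the latter the cell cycle (median -0.05, percentile 0.20). About 11.1 would fall outside on both sides together if genes moved independently, so the number outside was near that. Pathways can share genes, so no conclusion is drawn from more lying below than above.

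Erythroid genes were high and most T cell genes low in all 4 libraries, although the labels name a T cell line. Of the lists fixed before the data, at least 80.0% of the erythroid and at most 31.7% of the T lineage members lay at 1 FPKM or more in every library, so a line of erythroid lineage sequenced under the Jurkat label is a candidate explanation. Whether erythroid cells were mixed into a culture mostly of Jurkat cells cannot be told from the T lineage list. Its share of at most 31.7% fell between the shares set for either answer. The median of this list over 41 members was 0 FPKM in the untreated library and at most 0.0923 FPKM, in the chidamide library. The core T cell genes named above, chosen after their values were seen, had at most 5 fragments each over the 4 libraries. A smaller share of Jurkat cells cannot be told apart from an erythroid line alone, since levels of the T lineage genes in Jurkat cells were not used here. Gene names detached from their values are argued against because 100% of the ribosomal protein genes lay among the highest 5% of genes. No biological explanation was tested, since the lineage does not vary with the design, and CD3D at 86.0, CD7 at 41.5 and CD3G at 6.14 FPKM in untreated cells remain unexplained.

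The decitabine library differed little from the untreated library. That both are 1 library under separate labels is argued against by their fragments, which differed by more than sampling (chi-square per degree of freedom 2.77, against 66.3 between untreated and chidamide). Changes with decitabine in the absence and presence of chidamide had a Spearman's rho of 0.0319. This argues against a shared effect on genes at large that is large beside the spread of the changes (robust SD 0.21 and 0.17). Noise lowers rho, so a shared effect that is small beside it cannot be excluded. Mitotic genes (medians -0.07 and -0.08) and mitochondrially encoded mRNAs (-0.17 and -0.06) were set apart below in both comparisons. A small shared effect on these stays open, as does a joint movement of their members without an effect. Silent genes being switched on by decitabine is argued against by a ratio of 1.02, with 97 genes at 0 fragments without and at least 3 with decitabine after thinning and 95 the reverse, and of 0.71 in the presence of chidamide. An effect at another time or dose was not tested.

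More genes were detected in the libraries with chidamide, and after thinning to equal fragments 79.3% of the gap remained, 1716 of 2163 genes, which argues against deeper sequencing as the whole source. An even background such as DNA would reach olfactory receptor genes, which these cells should not express, as often as others. At most 5.44% of those silent without chidamide were detected with it, against 32.3% of other silent genes, although gene lengths were not matched. At 1 FPKM or more there were 0 of 331 olfactory genes against 155 and 164 of 5923 others, where 8.66 and 9.16 would appear if they were alike. A possible explanation that stays open, and was not itself tested, is expression of silent genes under deacetylase inhibition.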
